A study of Mus musculus with 2 samples.

How the data were processed

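Total RNA was measured in the left cerebral cortex of 2 male mice, which the labels give as biological replicates 1 and 2 of a single group. Per the labels, the mice were 8 to 10 months old, the strain was 5xFAD crossed with CAST, and 300 ng of RNA went into each library. Per the labels' protocols, the RNA was purified with a tissue column kit and the libraries were made with a directional kit from ribosomal RNA-depleted material with spike-in RNA of the External RNA Controls Consortium. The 2 samples carry separate biosample labels and the same strain-level donor label. With 1 group there was no contrast between groups and no p-value was computed; every statement on the 2 libraries describes those libraries.

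The authors deposited, per library, a gene table and a transcript table whose headers are those that RSEM writes, and a transcript table whose header is that which kallisto writes. Per the file headers, the RSEM-format tables hold expected counts, TPM and FPKM, and the transcript table also holds the percent that each transcript takes of its gene. Per the file headers, the kallisto-format table holds estimated counts and TPM per transcript. A deposited text description names mm10 as the genome build and M21 as the annotation, and says that the RSEM-format tables came from alignments to the transcriptome and the kallisto-format table from the reads themselves. The aligner, the program versions, the strand setting and any filter on reads are not given in the sources used here. In the deposited RSEM-format tables, the effective length was the length minus 100 bases for every entry longer than that. The deposited TPM are shares of all entries of a table, spike-ins included, so an abundant short RNA lowers the TPM of the other genes. Deposited posterior mean counts were not used here.

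The gene table held 55536 genes, all of which matched the reference annotation of mm10 by identifier, and 96 spike-ins, which were kept apart from the genes, as were tRNA entries and the phiX174 sequencing control. The kallisto-format table lacked 86 of the genes; its transcripts were summed per gene. Levels are deposited TPM, as the mean ± SD of the 2 animals. The level of a gene list is the median of its members' mean TPM. A gene counted as detected at a TPM of at least 1 in both libraries. Correlations were taken across genes on log2(TPM + 1); genes are not independent replicates. Gaps between lists were differences, per animal, of medians of log2(TPM + 0.1). Expected counts were rounded to whole numbers before edgeR and before every counting interval. The biological coefficient of variation came from edgeR with an intercept-only design, on genes with at least 10 reads in both libraries, after TMM normalization.

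Differences between the animals are log2 ratios of replicate 2 over replicate 1, so that a negative value is a higher level in replicate 1. Expected counts were scaled by TMM effective library sizes with 0.5 reads added to each library. A gene counted as different where the ratio was at least 2-fold, 1 library held at least 10 reads and the 99.9% Clopper-Pearson interval of the split of its reads excluded equal levels. Printed intervals are 95% Clopper-Pearson intervals. Where 1 library held 0 reads, a lower bound of the fold is given, with the floor of 3 reads in that library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and the spread between animals is not in them. For a gene list, the median log2 ratio over members with a mean count of at least 10 was set against 10000 random lists of the same size matched in 20 bins of mean count, and stood outside where it lay beyond the central 95% of them. Of 38 lists, about 1 in 20 would do so by chance if their members varied independently.

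The design, the 38 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the alternatives named as added below. The lists hold markers of excitatory neurons, inhibitory neurons, synapses, astrocytes, reactive astrocytes, homeostatic microglia, plaque-associated microglia, oligodendrocytes, their precursors, endothelium, mural cells, meninges and fibroblasts, choroid plexus, ependyma, blood, and border macrophages and lymphocytes. Others hold markers of striatum, hippocampus, thalamus and hypothalamus, olfactory bulb and cerebellum. The remaining lists hold complement genes, genes of amyloid precursor processing, Alzheimer risk genes, immediate early genes, and genes of the heat shock, interferon and glucocorticoid responses. They also hold genes of antigen presentation, cholesterol synthesis, the circadian clock, the mitochondrial genome, the nuclear respiratory chain and the ribosome, nuclear long noncoding and small structural noncoding RNAs, sex-linked genes, and the mouse genes related to the transgenes. Named genes were the sex-linked genes, App and Thy1, the 10 genes with the highest mean TPM, in each list up to 4 members with the highest TPM and up to 2 with the largest ratio between the animals at a mean count of at least 50, and the genes of the isoform list. To these were added, per direction, the 10 genes with the largest ratio among different genes with a mean count of at least 100, and the 10 genes that the quantifications placed furthest apart. The symbol Rmrp has 2 identifiers, whose TPM were summed for levels.

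Sequence sharing was measured by taking a word of 31 bases at every 10 bases of a gene's longest transcript. Each word was looked up in the transcripts of all other genes. A gene with at least 50% of its words in another gene is called a gene of shared sequence, and how the authors' counting split such reads is uncertain. The strand setting is unknown, so levels of genes that overlap a gene on the opposite strand are uncertain too. Reads of the human transgenes were not analysed here, and no value separates the alleles of the crossed strains. Dominant isoform shares were taken from deposited transcript TPM for 12 genes.

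The counting rule was tested on simulated counts of 19484 genes, of which 200 were changed. With counting noise and the observed spread, 93.5% of genes changed 4-fold, 40.5% of those changed 2-fold and 1.0% of those changed 1.5-fold were found, with 4 to 10 unchanged genes found. A coefficient of variation of 5, 10 and 20% was recovered as 4.98, 9.96 and 20.1%. For the list test, ratios were simulated as independent across genes. There, of 200 random lists of 12 genes, 94.5% stood inside the central 95%, and 100% of 200 lists shifted by 0.5 were found. Lists of co-expressed genes and smaller shifts were not simulated.

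Alternatives changed the TPM minimum, the pseudocount, the low-count filter, the fold minimum, the normalization (DESeq2 size factors, total count, spike-in totals, deposited TPM ratio), the TPM denominator, the unit (FPKM), the quantification (kallisto-format table) and the replicate left out. Removing a trend over GC content and transcript length from the ratios, and leaving out genes of shared sequence, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.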

Results

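Total RNA of the left cerebral cortex was sequenced from 2 male mice of the strain 5xFAD crossed with CAST, aged 8 to 10 months. The 5xFAD line carries human transgenes with mutations of familial Alzheimer disease, among them the amyloid precursor protein, driven by the Thy1 promoter, and it deposits amyloid plaques in the cortex. CAST is a wild-derived inbred strain. Both libraries belonged to the same group, and no animals without the transgenes were analysed here, so the data give levels in this cortex and differences between its 2 animals, without replication of any such difference. The expected counts summed to 34101499 reads in replicate 1 and 32543032 in replicate 2, of which 33925221 and 32380330 fell on annotated genes. At these depths the floor of 3 reads corresponded to 0.0884 and 0.0926 CPM.

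Small structural RNAs and mitochondrial transcripts had the highest TPM in these ribosomal RNA-depleted libraries. The ranking is by TPM, which weighs short RNAs more than their reads do, and it does not rank all RNA of the cortex. Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, stood at 129231 ± 8826 TPM each (SD, n = 2), with identical values in both animals. Rn7sk, the RNA that restrains the elongation factor P-TEFb, stood at 67984 ± 835 TPM, mt-Rnr2 and mt-Rnr1, the mitochondrial ribosomal RNAs, at 50673 ± 2188 and 39815 ± 628 TPM, and Rpph1, the RNA of ribonuclease P, at 5882 ± 295 TPM. Gm26917, a noncoding gene, reached 11165 ± 144 TPM. The other abundant genes were mt-Co1, a subunit of cytochrome oxidase, at 7188 ± 155 TPM, and Gm28661 and Gm10925 at 8234 ± 125 and 6411 ± 89.1 TPM. The last pair lie on nuclear chromosome 1 and had 100% of their sampled sequence in another gene, and mt-Co1 had 65.1%, so that the split of reads among them is uncertain.

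Protein-coding genes of the nuclear genome took 77.4% of the reads in replicate 1 and 79.1% in replicate 2. The mitochondrial chromosome took 10.6% and 9.42% (95% Clopper-Pearson intervals 10.60 to 10.62% and 9.41 to 9.43%), of which mitochondrial ribosomal RNA made up 8.19% and 7.29% of all reads. Long intergenic noncoding genes took 4.12% and 4.30%, miscellaneous RNA genes 5.11% and 4.46%, and the spike-ins 0.516% and 0.499%. The 10 genes with the highest mean TPM held 17.0% and 15.2% of the reads but 47.0% and 44.1% of the TPM, because several of them are short. Of 55536 annotated genes, 14843 had a TPM of at least 1 in both animals, among them 13083 of 22028 protein-coding genes and 273 long intergenic noncoding genes. A further 451 genes reached this level in replicate 1 only and 789 in replicate 2 only.

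Y-linked genes were expressed in both animals, and Xist, the RNA that silences the inactive X chromosome of females, was near the floor. Eif2s3y stood at 22.4 ± 2.97 TPM, Ddx3y at 20.4 ± 1.06, Uty at 10.3 ± 1.95 and Kdm5d at 7.66 ± 0.311 TPM. Xist had 6 reads in replicate 1 and 1 in replicate 2, and was listed at 0.03 and 0 TPM.

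App, the mouse amyloid precursor protein gene (ENSMUSG00000022892.11, mm10 chromosome 16, 84949685 to 85173766), stood at 593 ± 34.6 TPM. Thy1, a neuronal surface glycoprotein gene whose promoter drives the transgenes (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579), stood at 1376 ± 184 TPM. Their log2 ratios between the animals were -0.01 and 0.13. In the kallisto-format table the same genes stood at 839 TPM for App and 1604 for Thy1. Reads of the human transgenes were not analysed here, and part of the mouse App counts cannot be excluded from stemming from them.

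Synapse genes had the highest median of the neuronal and glial lists. The 20 synapse genes had a median of 176 TPM (163 in replicate 1 and 188 in replicate 2), led by Snap25, a SNARE protein of synaptic vesicle fusion, at 1243 ± 106 TPM and the vesicle proteins Syp at 772 ± 67.01, Syt1 at 445 ± 46.0 and Vamp2 at 443 ± 26.4 TPM. Excitatory neuron markers had a median of 34.9 TPM (33.5 and 37.2). Among them, the calcium-dependent kinase gene Camk2a stood at 957 ± 15.8 TPM, Nrgn at 659 ± 60.2, the vesicular glutamate transporter gene Slc17a7 at 450 ± 37.6 and Arpp21 at 294 ± 15.7 TPM. Inhibitory neuron markers had a median of 20.97 TPM (20 and 21.9), with the glutamate decarboxylases Gad1 at 173 ± 5.36 and Gad2 at 60.1 ± 2.20 TPM and the neuropeptides Sst at 159 ± 0.106 and Npy at 69.0 ± 9.44 TPM.

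The medians of astrocyte and oligodendrocyte markers lay between those of synapse genes and excitatory neuron markers. The astrocyte list had a median of 64.0 TPM (61.7 and 66.4), with the glutamate transporters Slc1a2 at 653 ± 15.2 and Slc1a3 at 132 ± 0.170 TPM and the glycolytic enzyme gene Aldoc at 369 ± 13.04 TPM. Oligodendrocyte markers had a median of 47.9 TPM (47.2 and 48.5), with the myelin genes Mbp at 765 ± 24.5, Mobp at 177 ± 2.46 and Cnp at 98.3 ± 2.57 TPM. Oligodendrocyte precursor markers had a median of 8.94 TPM (8.85 and 8.97). The transcription factor genes Olig1, Sox10 and Olig2 stood at 42.2 ± 2.91, 14.6 ± 0.424 and 9.94 ± 0.205 TPM, and Pdgfra, a growth factor receptor gene of these precursors, at 17.3 ± 0.841 TPM.

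Microglial and inflammatory genes were expressed at moderate levels, with a few glial genes of reactive or plaque-associated states among the more abundant transcripts. The 22 plaque-associated microglia genes had a median of 15.2 TPM (15.8 and 15.0), led by the lysosomal proteases Ctsd at 376 ± 16.7, Ctsb at 253 ± 6.92 and Ctsz at 59.6 ± 2.40 TPM and the adaptor gene Tyrobp at 105 ± 1.36 TPM. Trem2, the microglial receptor that signals through Tyrobp, stood at 42.4 ± 1.56 TPM. Homeostatic microglia genes had a median of 13.8 TPM (14.4 and 13.2), with the receptor genes Csf1r at 64.3 ± 5.59, P2ry12 at 33.9 ± 1.10 and Cx3cr1 at 27.8 ± 1.68 TPM. Of the reactive astrocyte genes, Gfap, the intermediate filament of astrocytes, stood at 274 ± 6.57 TPM, the complement gene C4b at 55.9 ± 2.66, Vim at 36.8 ± 1.77 and Serpina3n at 22.5 ± 1.81 TPM, while the list's median was 3.04 TPM (3.19 and 2.88). C4b had 48.6% of its sampled sequence in another gene. Complement genes had a median of 12.98 TPM (12.4 and 13.5), with the 3 chains of the recognition protein C1q, C1qa, C1qb and C1qc, at 56.7 ± 1.07, 54.4 ± 4.65 and 43.6 ± 2.66 TPM and C3 at 0.855 ± 0.318 TPM.

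To set the plaque-associated against the homeostatic microglial state, the log2 level of the first list was compared with that of the second within each animal. The plaque-associated list lay above the homeostatic list by 0.14 in replicate 1 and 0.17 in replicate 2, a mean of 0.16 ± 0.03 (SD, n = 2). This gap is larger than the spread between the animals but small beside the range within each list. It is a level and not a change, since no plaque-free animal was analysed here and the lysosomal genes of the plaque-associated list are expressed in neurons too.

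Among genes tied to Alzheimer disease, the risk gene list had a median of 16.3 TPM (16.9 and 15.6). The apolipoprotein genes Apoe and Clu stood at 1156 ± 78.6 and 454 ± 6.06 TPM, the kinase gene Ptk2b at 163 ± 10.7, Mapt, which encodes tau, at 153 ± 6.89 and Bin1 at 108 ± 9.03 TPM. The amyloid precursor processing list had a median of 27.5 TPM (26.0 and 29.0), with the App relatives Aplp1 and Aplp2 at 543 ± 13.9 and 249 ± 22.4 TPM and Itm2b at 363 ± 16.6 TPM. Antigen presentation genes had a median of 13.8 TPM (12.8 and 14.8), led by B2m at 106 ± 0.672 and Cd74 at 47.1 ± 0.969 TPM. Interferon response genes had a median of 1.45 TPM (1.17 and 1.72), although Ifi27 stood at 44.4 ± 0.0354 TPM.

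**Figure D1:**
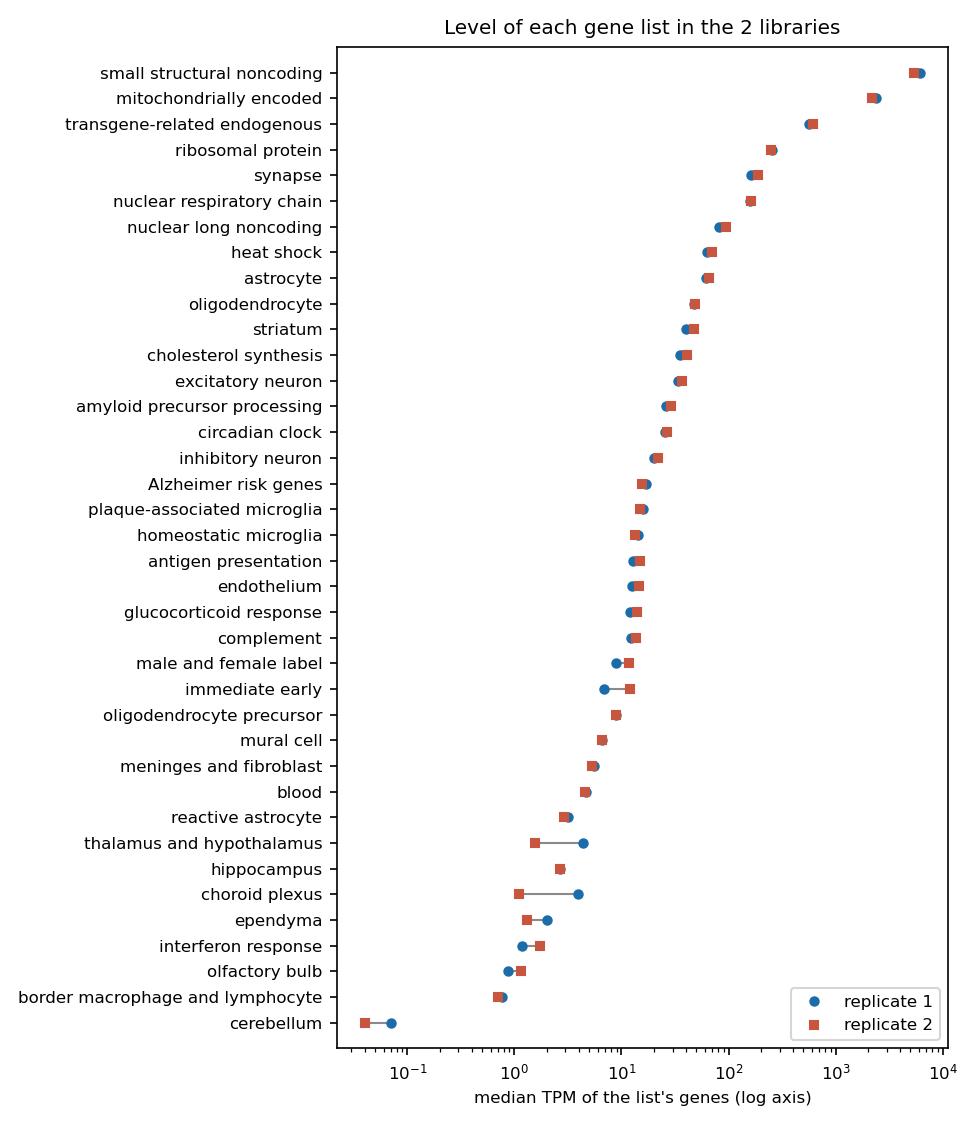
Median TPM of the genes of each of the 38 lists (horizontal log axis), with replicate 1 as a blue circle and replicate 2 as a red square, joined by a grey line. Synapse genes lie at 163 and 188 TPM and cerebellar markers at 0.07 and 0.04 TPM, and the choroid plexus list is among the few in which the symbols lie well apart.

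Endothelial markers stood near the microglial lists, and markers of mural and border cells below them. Endothelial markers had a median of 13.8 TPM (12.6 and 14.6), with the glucose transporter gene Slc2a1 at 40.9 ± 5.88 TPM, and mural cell markers 6.64 TPM (6.63 and 6.65), with Vtn at 35.0 ± 1.23 and Rgs5 at 18.5 ± 0.304 TPM. Meningeal and fibroblast markers had a median of 5.45 TPM (5.59 and 5.31) and were led by Igf2 at 44.1 ± 10.2 TPM, which has 76.0% of its sampled sequence in another gene. Border macrophage and lymphocyte markers had a median of 0.750 TPM (0.765 and 0.705). Blood genes had a median of 4.60 TPM (4.64 and 4.57), with the hemoglobin genes Hba-a1 at 98.9 ± 4.23, Hbb-bs at 87.6 ± 12.9 and Hba-a2 at 79.5 ± 17.9 TPM, whose shared sequence leaves their split uncertain.

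Mitochondrial, small structural and ribosomal protein genes stood at the upper end. Mitochondrially encoded genes had a median of 2266 TPM (2373 and 2184), with mt-Co3 at 5593 ± 696, mt-Cytb at 3911 ± 72.5 and mt-Nd1 at 3681 ± 189 TPM. Small structural noncoding RNAs had a median of 5788 TPM (6169 and 5407), ribosomal protein genes 249.6 TPM (252.7 and 249.2), with Rplp1 at 709.6 ± 0.445 and Rps29 at 658 ± 38.2 TPM, and nuclear respiratory chain genes 162 TPM (158 and 164), with Atp5b at 747 ± 8.13 and Cox4i1 at 512 ± 7.59 TPM. Nuclear long noncoding genes had a median of 88.0 TPM (81.3 and 94.7), led by Malat1 at 3618 ± 754 and Meg3 at 961 ± 200 TPM. Heat shock genes stood at 66.9 TPM (63.6 and 70.1), with Hspa8 at 741 ± 15.5 TPM, cholesterol synthesis genes at 38.5 TPM (35.3 and 40.7), with Hmgcs1 at 124 ± 13.5 TPM, and circadian clock genes at 25.7 TPM (25.4 and 26.4), with Tef at 116 ± 11.8 and Dbp at 78.4 ± 10.9 TPM. Glucocorticoid response genes stood at 13.01 TPM (12.1 and 13.9), with Sgk1 at 50.8 ± 11.1 TPM, and immediate early genes at 10.1 TPM, with medians of 6.93 in replicate 1 and 12.1 in replicate 2. The sex-linked and transgene-related lists had medians of 10.3 and 593 TPM.

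The excitatory neuron list was set against markers of other regions within each animal. The gaps are between levels of different genes, without reference tissue, so they do not measure how much of a region was present. The excitatory neuron list lay above the markers of hippocampus by 3.63 ± 0.11 on the log2 scale (SD, n = 2). It lay above those of olfactory bulb by 4.94 ± 0.15 and of cerebellum by 7.78 ± 0.30. All these gaps were larger than the spread between the animals. The medians of these lists were 2.67, 1.02 and 0.0550 TPM. Wfs1, a hippocampal CA1 marker that cortex also expresses, stood at 59.7 ± 3.56 TPM, and the cerebellar gene Cbln1 at 5.00 ± 0.601 TPM. Striatal markers stood slightly above those of excitatory neurons: the excitatory neuron list lay below them by 0.32 in replicate 1 and 0.40 in replicate 2, a mean gap of -0.36 ± 0.06. Their median was 43.9 TPM (40.3 and 47.5), with the dopamine signalling gene Ppp1r1b at 214 ± 20.9, the opioid peptide gene Penk at 162 ± 18.6 and Pde10a at 76.0 ± 10.6 TPM. With a pseudocount of 1, the gap to the cerebellar markers, most of which are near 0, was 5.05.

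Markers of tissue around the ventricles separated the animals. The gap between the excitatory neuron list and the choroid plexus markers was 3.96 ± 1.36 (SD, n = 2), the larger at 4.92 in replicate 2, and that to the markers of thalamus and hypothalamus was 2.88 in replicate 1 and 4.52 in replicate 2. The corresponding gaps were 3.95 and 4.66 for ependyma and 2.51 and 2.73 for meninges and fibroblasts. In TPM, the choroid plexus list stood at 3.94 and 1.11, that of thalamus and hypothalamus at 4.35 and 1.55, and that of ependyma at 2.03 and 1.33.

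Across genes, the 2 libraries were close. Pearson's r of log2(TPM + 1) over 55536 genes was 0.994 and Spearman's rho 0.939. The correlation is across genes, which are not independent replicates. The biological coefficient of variation between the animals, estimated by edgeR over 18161 genes, was 6.34%. Over all 96 spike-ins, of which 58 had a read in both libraries, r was 0.992 on log2(TPM + 0.1). By counting error alone, which leaves out the spread between animals, 1713 of 19484 genes with at least 10 reads in a library, or 8.79%, had an interval by the counting rule that excluded equal levels. Over all 19484 genes, the median absolute log2 ratio was 0.13 and 85.8% lay under 0.5.

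By the counting rule, 111 genes were at least 2-fold higher in replicate 2 and 126 at least 2-fold higher in replicate 1, of which 49 and 80 were protein-coding. Ttr, which encodes transthyretin, the main secreted protein of the choroid plexus (ENSMUSG00000061808.4, mm10 chromosome 18, 20665280 to 20674321), was higher in replicate 1, with 14495 reads against 2451 and 534 TPM against 101, a log2 ratio of -2.53 (95% counting interval -2.59 to -2.47). Also higher in replicate 1 were Tmem72 at -1.99 (-2.38 to -1.62), Mfrp at -1.87 (-2.39 to -1.40) and Sostdc1, a secreted inhibitor of BMP and Wnt signalling, at -1.86 (-2.34 to -1.43). Higher in replicate 2 were the immediate early transcription factor genes Fos at 1.53 (1.29 to 1.77), Nr4a1 at 1.40 (1.28 to 1.51) and Egr2 at 1.23 (0.87 to 1.61). Tmem72 stood at -0.03 in the kallisto-format table and did not meet the rule there. The intervals cover counting error only.

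The other genes with the largest ratios at a mean count of at least 100 shared their sequence with another gene, so the split of their reads between copies is uncertain. Higher in replicate 2 were the copy of the transhydrogenase gene Nnt at chromosome 13, 119335528 to 119408952, at least 99.8-fold, Pagr1a at least 89.5-fold and Gm10359 at least 83.7-fold, all with fewer than 1 read in replicate 1, and Nnt and Pagr1a met the rule in the kallisto-format table too. So were Myl12b (ENSMUSG00000117098.1) at 2.75, Gm20388 at 1.91, Gm11847 at 1.86 and the histone gene Hist1h4n at 1.201. Higher in replicate 1 were Gm10222, a nuclear copy of mitochondrial sequence, at least 184-fold with 0 reads in replicate 2, the histone gene Hist1h2ap at -2.61, and one annotated entry each of the U3 small nucleolar RNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 at -1.97. The other entry of each stood at 0.03. In the kallisto-format table, Myl12b stood at -2.76, Gm11847 at -1.33 and Hist1h4n at -1.06, in the opposite direction, and Gm20388 at 0.59 and Hist1h2ap at -0.86, below 2-fold. Genes of shared sequence made up 66 of the 111 genes and 68 of the 126, against 6.89% of the other tested genes. Without them, 45 and 58 genes remained, an alternative chosen after seeing the data. Of the 111 and 126 genes, 39 and 55 also met the rule in the kallisto-format table, which gave 188 and 111 genes in all.

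**Figure D2:**
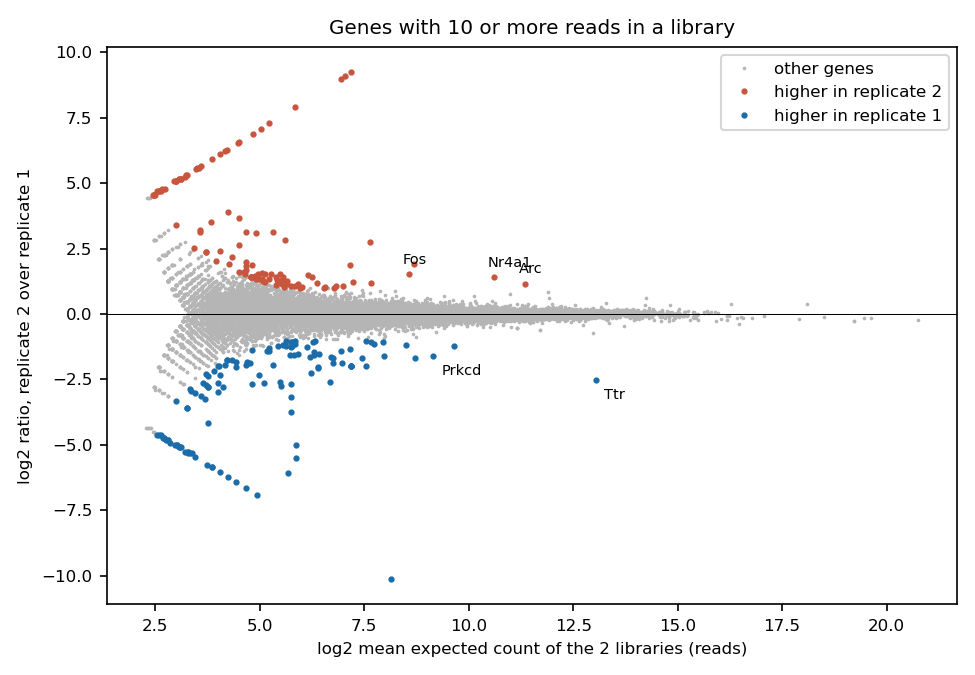
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against the log2 mean expected count in reads (horizontal axis) for 19484 genes, each a point, with the 111 genes higher in replicate 2 in red and the 126 higher in replicate 1 in blue. The rays of points at the left are genes with 0 reads in a library, whose plotted ratio depends on the 0.5 reads added, and Ttr at -2.53 lies apart from all other genes of similar count.

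Of the 38 gene lists, 18 lay outside the central 95% of matched random lists. For lists whose members vary independently, chance gives about 1 in 20. The largest difference was in the choroid plexus list: all 10 members met the rule and were higher in replicate 1, with a median log2 ratio of -1.77 against -0.17 to 0.18 for random lists. Examples are the anti-ageing hormone gene Kl, with 5.17 and 1.76 TPM, at -1.68, the bicarbonate transporter gene Slc4a5 at -2.05 and the potassium channel gene Kcnj13 at -1.54. Markers of thalamus and hypothalamus had a median of -1.08, with all 8 measured members below 0 and 4 of them meeting the rule, among them Prkcd, a protein kinase C gene strong in thalamic relay neurons, at -1.61 (15.3 and 6.99 TPM). Tcf7l2 at -0.77, Plekhg1 at -0.54 and the vasopressin gene Avp at -0.93 did not meet the rule. The 4 measured ependymal markers had a median of -0.57, with the ciliary regulator Foxj1 at -0.57 and Rsph1 at -0.08. At a mean count of at least 50 the ependymal median was -0.33 and lay inside the random range.

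Immediate early genes were higher in replicate 2. All 14 members had ratios above 0, with a median of 0.61 against -0.09 to 0.08 for random lists, and 4 met the rule: Fos, Nr4a1 and Egr2, above, and Arc, a synaptic plasticity gene, with 22.1 and 53.9 TPM, at 1.16 (1.07 to 1.24). Egr1 at 0.84 and Junb at 0.69 were below 2-fold. Nuclear long noncoding genes had a median of 0.35, with 8 of 9 members above 0, among them Malat1 at 0.38, Meg3 at 0.38, Mirg at 0.43, Miat at 0.42 and Snhg11 at 0.35. Circadian clock genes had a median of 0.16, with 11 of 14 above 0, the period gene Per1 at 0.60 and Ciart at 0.59. Cholesterol synthesis genes had a median of 0.11, with 11 of 16 above 0, including Lss at 0.24. No member of these last 3 lists met the rule.

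Glial lists lay slightly towards replicate 1, with no member that met the rule. The median was -0.21 for plaque-associated microglia, with 21 of 22 members below 0, -0.16 for homeostatic microglia, with all 12 below 0, and -0.25 for complement, with 8 of 9 below 0. Examples are the chemokine gene Ccl3, with 107 reads against 52, the osteopontin gene Spp1 at -0.67, C3 at -0.68 and Cx3cr1 at -0.25. Reactive astrocyte genes had a median of -0.19, with all 10 measured members below 0, including Serpina3n at -0.29 and Gfap at -0.18. The medians were -0.12 for astrocytes, with all 12 below 0, -0.12 for oligodendrocytes, with 11 of 12 below 0, -0.10 for their precursors, with 8 of 10 below 0, and -0.14 for meninges and fibroblasts, with 8 of 11 below 0 and Igf2 at -0.49. Deposited TPM moved the median ratio of all genes to 0.12. On that scale these last 4 medians turned positive, at 0.02, 0.02, 0.07 and 0.10, and the precursor and meningeal lists lay inside the random range. The medians there were -0.09 for plaque-associated microglia, with 15 of 22 below 0, -0.08 for homeostatic microglia, with 11 of 12, -0.04 for complement, with 5 of 9, and -0.06 for reactive astrocytes, with 7 of 10. Spike-in totals raised the median ratio of all genes to 0.08, with medians of -0.04 for astrocytes and for oligodendrocytes, a shift that the random lists share.

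Some transcript classes were higher in replicate 1 as well. Mitochondrially encoded genes had a median of -0.23, with all 13 below 0, and mt-Co2 at -0.43 and mt-Co3 at -0.38. Both share 100% of their sampled sequence with another gene. With deposited TPM the median was -0.10, with all 13 below 0. Ribosomal protein genes had a median of -0.13, with 19 of 20 below 0, including Rps29 at -0.25 and Rplp0 at -0.22. Their median was -0.05 with spike-in totals, and -0.00478 with deposited TPM, with 11 of 20 below 0. Without a trend over GC content and transcript length it was -0.08, outside the random range. Small structural noncoding RNAs had a median of -0.27, with 6 of 7 below 0, including Rmrp, the RNA of ribonuclease MRP, at -0.46. That is the annotated copy with more reads, and the other, not counted in the list, stood at -0.35. The median is the value of both Rn7s1 and Rn7s2, whose counts were identical. Once that trend was removed, an alternative chosen after seeing the data, the last list lay inside the random range at -0.04, and with deposited TPM it stood at -0.14, with 5 of 7 below 0.

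The other 20 lists lay inside the range of random lists, though 6 of them did not under every alternative. Mural cells lay outside it at a mean count of at least 50, at -0.19, in the kallisto-format table, at -0.18, and without the GC and length trend, at -0.15. The nuclear respiratory chain list lay outside in 3 alternatives, striatum in 1, and inhibitory neurons, synapses and the glucocorticoid response in the kallisto-format table. With TMM scaling the medians were 0.04 for excitatory neurons, 0.03 for synapses, -0.07 for inhibitory neurons, 0.01 for amyloid precursor processing, -0.03 for Alzheimer risk genes, -0.01 for endothelium, -0.13 for mural cells, 0.05 for striatum, -0.08 for hippocampus, -0.06 for olfactory bulb and -0.16 for cerebellum. They were -0.01 for blood, -0.07 for border macrophages and lymphocytes, -0.03 for heat shock, 0.09 for the interferon response, -0.08 for antigen presentation, 0.06 for the glucocorticoid response, -0.05 for the nuclear respiratory chain, and 0.01 each for the sex-linked and transgene-related lists. Single members of these lists stood further out. Examples are the inhibitory neuron gene Calb2, which encodes calretinin, at -0.87 (-1.07 to -0.66), and the smooth muscle genes Tagln at -0.63 and Acta2 at -0.40. Others are the tight junction gene Cldn5 at -0.36, the hippocampal granule cell gene Prox1 at -0.41 and Aph1c at 0.45. Eomes, with 31 and 4 reads, and Dsp of the hippocampal list, with 70 and 29 reads and a ratio of -1.22, met the rule.

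**Figure D3:**
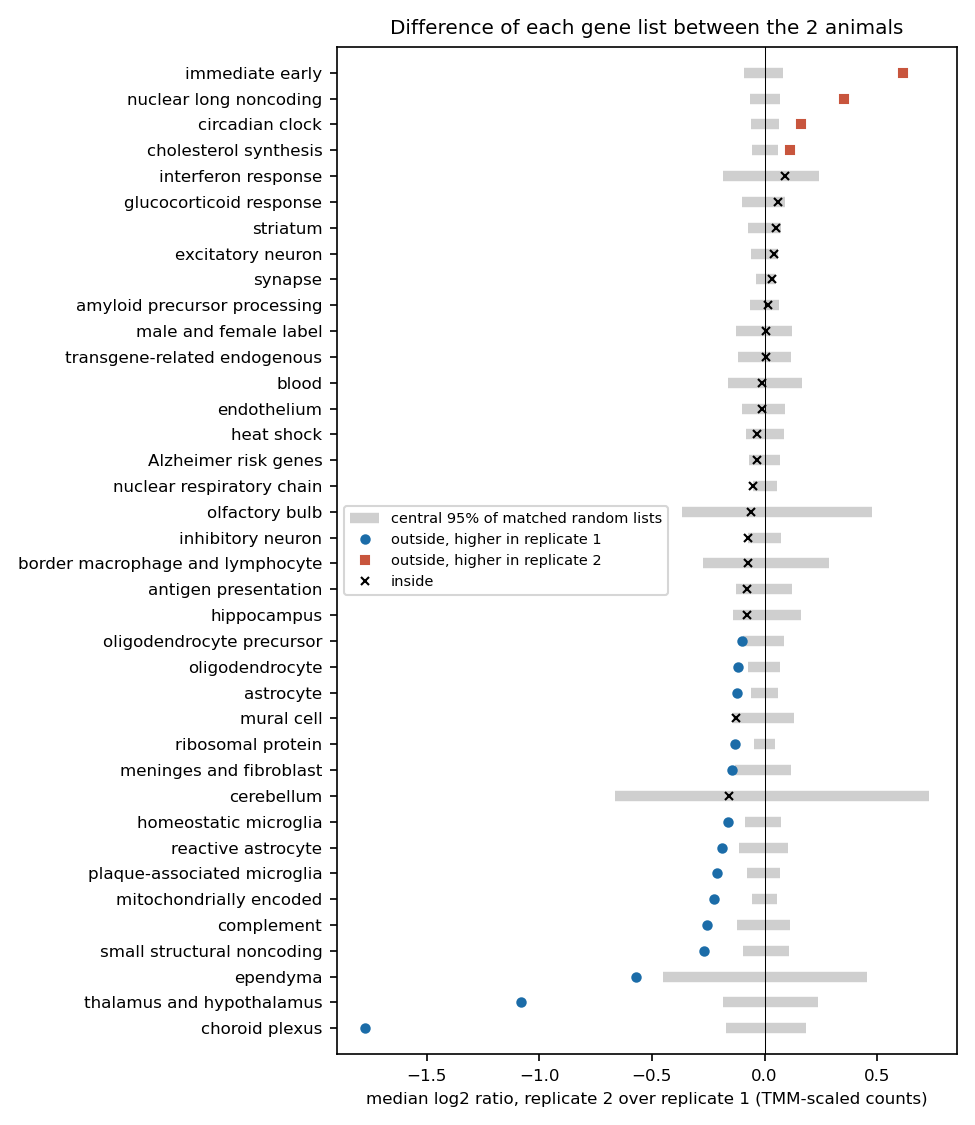
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis) of each of the 38 gene lists, with grey bars for the central 95% of matched random lists; blue circles are lists outside it and higher in replicate 1, red squares lists outside it and higher in replicate 2, crosses lists inside it. Choroid plexus at -1.77 and immediate early genes at 0.61 lie furthest out in their directions; with deposited TPM the medians of astrocytes, oligodendrocytes, their precursors, and meninges and fibroblasts are above 0.

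Each of 12 genes had the same dominant transcript in both transcript tables. App-201 took 90.5% ± 0.145 of the TPM of App (SD, n = 2), Clu-201 97.2% ± 0.0548 of Clu, Apoe-209 85.4% ± 1.33 of Apoe and Snap25-201 83.5% ± 0.000977 of Snap25. Mapt-204 took 66.8% ± 1.38 of Mapt, Mbp-211 70.0% ± 1.21 of Mbp and Gria2-202 52.4% ± 0.190 of Gria2, a glutamate receptor gene. Thy1-201 took 51.7% ± 0.586 of Thy1, with the noncoding Thy1-203 at 47.1% ± 0.586, and Bin1-201 took 50.5% ± 0.0731 of Bin1. The animals lay well apart in Trem2, in which Trem2-201 took 86.3% in replicate 1 and 73.4% in replicate 2. In the kallisto-format table, Mbp-211 took 43.1%, Apoe-209 52.9% and Clu-201 75.6%, so these shares depend on the quantification more than on the animal.

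**Figure D4:**
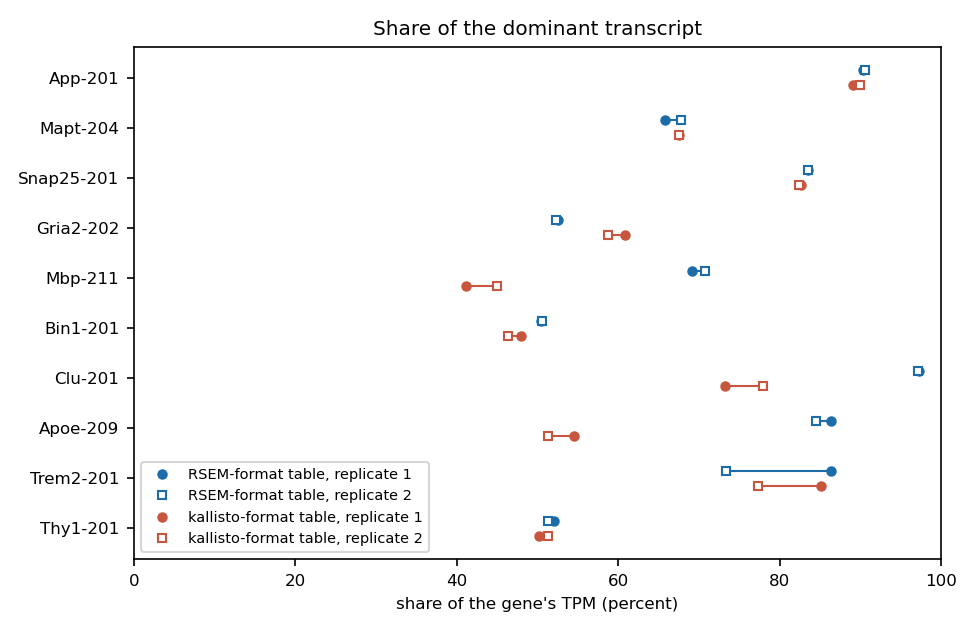
Share of each gene's TPM taken by its dominant transcript (horizontal axis, percent) for 10 of the 12 genes, in the RSEM-format table in blue and the kallisto-format table in red, with a filled circle for replicate 1 and an open square for replicate 2, joined by a line. For Mbp-211, Apoe-209 and Clu-201 the tables lie further apart than the animals.

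The 2 quantifications of the same reads gave similar ranks of genes, with a Spearman's rho across genes of 0.908 in each library. Of 8718 genes with a mean TPM of at least 10, 234, or 2.68%, were at least 2-fold apart in the same direction in both libraries, of which 161 were lower and 73 higher in the kallisto-format table. Nearly all genes of 3 small RNA classes differed: 23 of 23 small nuclear RNA genes and 6 of 6 microRNA genes were lower in that table, and of 49 small nucleolar RNA genes 46 were lower and 1 was higher. Of 166 processed pseudogenes, 53 were lower and 16 higher, and of 8281 protein-coding genes 14 and 27. Rnu1a1, a U1 small nuclear RNA gene, and its copies Gm22317, Gm23804, Gm22068, Gm25679 and Gm22634 stood at 796 ± 22.8 TPM in the RSEM-format table and were listed at 0 in the other. So were Gm24265 at 1402 ± 153, Gm24407 at 1289 ± 39.2 and Snurf, a short gene on chromosome 7, at 1059 ± 19.7 TPM. Gm19220, a processed pseudogene, was listed at 0 in the RSEM-format table and stood at 1498 ± 778 TPM in the other. Except for Gm19220, these genes had 66.7% or more of their sampled sequence in another gene, so their levels are uncertain in both tables.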

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

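All tests of explanations below had their predictions written before their values were computed, but the patterns were picked after the differences between the animals had been seen. Reads outside the main measurement were found in both libraries. The phiX174 sequencing control had 215 reads in replicate 1 and 174 in replicate 2, above the limit of 3 that a count of 0 allows. The tRNA entries had 4.92 reads in replicate 2, also above it, and 3 in replicate 1.

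The first pattern is the higher level in replicate 1 of markers of choroid plexus, ependyma, and thalamus and hypothalamus. Their list medians were -1.77, -0.57 and -1.08. The last list includes the hypothalamic neuropeptide genes Pmch at -2.64, Oxt at -1.40, Avp at -0.93 and Pomc at -0.03. A trend over GC content and transcript length is argued against, since the choroid plexus median was still -1.76 with that trend removed. A candidate explanation is that the piece dissected from replicate 1 held more tissue from around the ventricle, and markers kept out of the first lists went the same way: the median was -0.63 over 17 choroid plexus genes, -0.33 over 13 ependymal genes and -0.50 over 12 thalamic genes, with all 17, all 13 and 11 of 12 below 0. Of these held-out lists, 10, 7 and 10 genes had a TPM of at least 1 in both animals, and none is in the fixed lists. They come from the same 2 libraries in which the pattern was seen, so they are not independent support. Without shared sequence, 8 of their genes were among those that met the rule. Tmem72 is 1 of these and did not meet the rule in the kallisto-format table. No held-out list covered the hypothalamus. Ttr, the most abundant marker, stood at 534 and 101 TPM. Hippocampal and striatal lists lay inside the random range at -0.08 and 0.05, although Dsp of the hippocampal list met the rule, higher in replicate 1. No biological explanation was tested, since both animals carry the same labels.

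The second pattern is the higher level of immediate early genes in replicate 2, with a median of 0.61. A GC and length trend is argued against, since the median with it removed was 0.62. Activity-dependent transcription before the tissue was taken may account for part of it: 28 further activity-induced genes had a median of 0.18, above all random lists, and 21 of them were above 0, but Maff at -0.78, Egr3 at -0.17, Nptx2 at -0.33 and Inhba at -0.35 were not, and Bdnf stood at 0.02. A larger share of nuclear RNA was tested by the excess of long intergenic noncoding over protein-coding genes, 0.077 (95% bootstrap interval over genes 0.04 to 0.12). The value and its whole interval lay below the excess predicted for that cause, a fixed share of the immediate early median. An excess under 0.1 was predicted without it, a bound that the interval spans. The nuclear long noncoding list, at 0.35 with 8 of 9 members above 0, goes with the explanation. That list had been seen when the pattern was picked, and its member Neat1 stood at -0.01. The explanation stays open. The labels give no time of collection, and they name no difference between the animals that could be tested.

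The third pattern is the set of 234 genes that the 2 quantifications placed at least 2-fold apart. Overlap with a gene on the opposite strand was predicted to be more common among the genes set apart. It was not, at 17.9% of them and 45.9% of the rest, a ratio of 0.391. Overlap was scored over whole gene bodies without matching on length, and many of the genes set apart are short. The test therefore cannot decide on this explanation. Short transcripts and shared sequence may both contribute: a mean transcript length under 300 bases was found in 107 of the 234 genes and 11 of the other 8484, a ratio of shares of 353, and at least 50% of sampled words in another gene in 173 and 380, a ratio of 16.5. One or the other property was present in 204 of the 234 genes. The tests do not say which table is nearer to the true level.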

How the results depend on the processing

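Removing the GC and length trend and leaving out genes of shared sequence were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the design holds 1 group of 2 animals and no comparison of groups. DESeq2 size factors, total counts and spike-in totals shift all genes alike, so they cannot move a list against its random lists and do not test the list calls. Spike-in totals raised every median by about 0.08, to -0.04 for astrocytes and oligodendrocytes and -0.05 for ribosomal proteins, and lists near 0, such as inhibitory neurons, Alzheimer risk genes and hippocampus, changed sign, as more did with deposited TPM. Of the lists outside the range, those that changed sign or came to lie inside it were, with deposited TPM, 0.0223 for astrocytes, 0.0164 for oligodendrocytes, 0.068 for their precursors and 0.10 for meninges and fibroblasts, a scale on which the median of all genes is 0.12. They were -0.33 for ependyma at a mean count of 50, -0.12 for meninges and fibroblasts in the kallisto-format table and -0.0399 for small structural noncoding RNAs without the trend. Lists inside the range that came to lie outside it were mural cells (-0.19) and the nuclear respiratory chain (-0.05) at a mean count of 50, the respiratory chain (0.06) with deposited TPM, and mural cells (-0.15) and striatum (0.07) without the trend. In the kallisto-format table they were inhibitory neurons (-0.10), synapses (0.02), mural cells (-0.18), the glucocorticoid response (0.10) and the respiratory chain (-0.07). The number of lists outside stayed between 17 and 22. The genes higher in replicate 2 and replicate 1 numbered 46 and 64 at 50 reads, which tests fewer genes, 45 and 58 without genes of shared sequence, and 188 (replicate 2) in the kallisto-format table, which reversed Gm11847 at -1.33, Hist1h4n at -1.06 and Myl12b at -2.76 and gave no value for Gm10222, Gm10359 and the 4 Rnu3b copies, which were at or under the floor there in both libraries. Pearson's r was 0.986 with a pseudocount of 0.1, 0.984 over genes with a mean TPM of at least 1 and 0.993 in the kallisto-format table; Spearman's rho was 0.986 and 0.947 in the last 2. The coefficient of variation was 6.55% with total counts and 6.78% in the kallisto-format table. That table gave gaps of 0.22 between the microglial lists and -0.27, 6.99 and 2.78 from excitatory neurons to striatum, cerebellum and meninges. With a pseudocount of 1 the gaps were 3.26 to hippocampus, 4.12 to olfactory bulb, 5.05 to cerebellum, 3.73 to ependyma and 2.44 to meninges. Genes set apart numbered 914 at a mean TPM of at least 1. Except for the filters, the cause was not tested. List levels moved by more than 1 SD in 30 of 38 lists when TPM were rescaled without spike-ins and mitochondrial genes and in 21 in the kallisto-format table, and 9 of 12 isoform shares did so in that table. Without replicate 1 or replicate 2, detected genes numbered 15632 and 15294, and the microglial gap was 0.17 and 0.14. In simulated libraries of this depth 40.5% of changes at the minimum of 2-fold and 93.5% of 4-fold changes were found, and 48.1% of 2-fold changes in genes with over 100 reads.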

Other observations

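The genes named in this part were chosen after their values were seen, and no explanation is offered for them. Some neuropeptide genes of the hypothalamus had more reads in replicate 1: Pmch, which encodes melanin-concentrating hormone, had 60 reads against 9, the oxytocin gene Oxt 54.5 against 20.3, and the orexin gene Hcrt 12 against 0. Others had similar counts: Pomc had 21 against 20 and Agrp 1 against 1.12. All of these belong to the fixed list of thalamus and hypothalamus, and Pmch, Oxt and Pomc entered its median. The thalamic transcription factor genes Shox2 and Zic1 had 113 reads against 3 and 1142 against 475. Of the 58 genes higher in replicate 1 without shared sequence, 23 belong to the fixed or held-out lists of choroid plexus, ependyma and thalamus. The fixed thalamic list also holds hypothalamic genes. Of the 45 genes higher in replicate 2, none belong to these lists. The lists were singled out because they lean to replicate 1, so this split largely follows from that choice.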
